A study of Arabidopsis thaliana with 16 samples.

How the data were processed

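Protein interaction profile sequencing (PIP-seq) was run on leaves 5 to 9 of 4-week-old Arabidopsis thaliana plants, in 16 libraries. Per the labels' protocols, plants grew under 12 hours of light per day at 22°C, and about 12 formaldehyde-crosslinked leaves were pooled for each replicate of each genotype. Each homogenate was split into a protein-bound and a structure-only fraction, and proteins were removed before digestion in the latter. Each fraction was then digested with a single-strand-specific RNase (ssRNase) or a double-strand-specific RNase (dsRNase), and strand-specific libraries were made. The genotypes were wild type (Col0) and ABI3:MTA (mta), with 2 replicates each, so that each replicate gave 4 libraries.

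The submitters' processing notes name cutadapt 1.2.1, TopHat2 2.0.10, STAR 2.4.0 and HTSeq, without their roles, and the build TAIR10. The authors deposited 4 lists of protein-protected sites (PPS), one list per genotype and replicate, and 2 tracks of structure scores, one track per genotype. The names of the deposited PPS lists give CSAR as the caller and a false discovery rate of 5%. Site names in these lists show that the authors called sites for each replicate and RNase and then merged overlapping calls, and each site carries the caller's score, which was used here only to rank sites within a list. The authors' structure score is given per nucleotide of each spliced transcript, from the structure-only libraries of both RNases with the replicates pooled. How this score was computed and which transcripts were kept is not given in the sources used here. The deposited scores are centred: the mean of each transcript lies within 0.005 of 0 in both tracks. That a higher score stands for more pairing follows the usual definition of such scores and is not stated in the files. The depth of the libraries is unknown, because the files used here hold no read counts, and no interval that needs depth is given. The tracks scored 82.1% (Col0) and 76.0% (mta) of the nucleotides of 13678 transcripts.

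Gene models were those of the score tracks, with 9564 genes, of which 88 are encoded in the chloroplast and 60 in the mitochondrion. Symbols came from a RefSeq gene table of assembly TAIR10.1, which held 9359 of these genes, and none of its coordinates were used. Coordinates are 1-based TAIR10 positions. The order of the scores along minus-strand transcripts was tested on the nucleotides shared by 2 isoforms of a gene. In this order the isoforms correlated at a median of 1 over 1438 genes, and at 0.324 over 1435 genes when reversed.

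PPS numbers, covered lengths and shares per feature were computed per list and compared with 2-sided exact permutation tests, 2 lists against 2. The smallest p-value this design allows is 0.333, so the values themselves are given. Overlap between lists was the number of shared nucleotides over all covered nucleotides on the same strand (Jaccard index). Annotated nucleotides were assigned to coding sequence (CDS), 3′ UTR, 5′ UTR, non-coding exon, intron or outside the genes of the tracks. A gene had a PPS in a list when at least 1 nucleotide of its exons was covered on the same strand. Genes with PPS in both lists of a single genotype were counted and set beside the counts for the 2 other ways of splitting the 4 lists into pairs.

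PPS coverage per gene was the number of exonic nucleotides covered by PPS. Each list was scaled to the mean covered total of the 4 lists, a pseudocount of 20 nucleotides was added, and log2 values of genes with PPS in at least 2 lists were fitted with limma 3.58.1 (lmFit, eBayes with trend and robust settings) in R 4.3.3. Log2 changes are on this scale, which understates the changes of genes with little coverage. The threshold was an adjusted p-value of 0.05 (Benjamini-Hochberg). Gene lists were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, adjusted over 14 lists. The lists covered m6A writers, readers and erasers, photosystems and light harvesting, carbon fixation, photorespiration, RNA-binding proteins, the circadian clock, cold, drought and salt response, defence, trichomes and leaf shape, translation elongation factors, and markers of guard cells and vasculature, of the epidermis and of seeds. Chloroplast-encoded and mitochondrion-encoded genes were added as lists after the data were seen. None of the 10 seed markers was among the genes of the tracks, and a list of cytosolic ribosomal proteins was not analysed here. The labels do not say that the replicates came from separate growths, so p-values measure the spread between these samples only.

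Structure scores were compared without a test, because each genotype had a single pooled track. The planned difference in the mean score of a transcript is fixed at 0 by the centring and was replaced by the Pearson correlation of the tracks along each transcript, over at least 100 nucleotides scored in both. Mean scores per 5′ UTR, CDS and 3′ UTR (at least 20 nucleotides) and in steps of 10 nucleotides around the start and the stop codon were computed on a single transcript per gene. Lists were placed among 10000 random lists of the same size, drawn gene by gene and matched on the scored nucleotides of the whole transcript. The length of a region was not matched. For PPS found in both replicates of a genotype, the mean score inside was compared with that of equally long flanks on both sides. Exact Clopper-Pearson 95% intervals over genes or sites cover counting error only, since genes and sites of a track are not replicates.

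Groups, tests, gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The rule named the 10 genes with the largest rise and fall among those past the threshold. Where fewer passed, it took genes with PPS in both lists of a single genotype, ranked by mean covered nucleotides, and a single gene of these is not reported here. It also named up to 4 members of each list with the largest absolute log2 change, and the 5 transcripts with the largest rise and fall in mean score. As that mean is void, the mean score of 3′ UTRs with at least 200 scored nucleotides was used in its place. Alternatives covered stricter PPS, the overlap rule, strand, gene body, pseudocounts of 1 and 100, no scaling, filters, a replicate block, each replicate left out in turn, transcript choice, minimum lengths and flanks of 50 nucleotides. PPS and scores at RRACH motifs, the sequence context of m6A, were not analysed here, as no genome sequence was used.

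Scripts were tested on simulated data. For PPS coverage in mta against Col0 over 3070 genes, the limma fit recovered 0% of simulated log2 changes of 1, 3.03% of changes of 2 and 62.1% of changes of 4, with 2 false calls. The simulated changes ignored the floor set by the pseudocount and the limit set by exon length. For the structure scores, a simulated median correlation of 0.707 was recovered as 0.705, a 3′ UTR shift of 0.20 as 0.198 and a shift inside PPS of -0.30 as -0.316. Other computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.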

Results

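Leaves of 4-week-old Arabidopsis thaliana were profiled by PIP-seq, which maps stretches of RNA protected by proteins and the pairing of RNA in crosslinked tissue. Of the 16 libraries, 8 came from wild-type plants (Col0) and 8 from ABI3:MTA plants (mta), with 2 replicates per genotype. MTA is a subunit of the methyltransferase that makes the mRNA modification m6A, and the ABI3 promoter is mainly active in seeds. The comparison asks how protein protection and RNA structure in mta leaves compare with those of wild type. The deposited data are 4 lists of protein-protected sites (PPS), one for each replicate, and 2 tracks of structure scores, in which the replicates are pooled. MTA and ABI3 are not among the 9564 genes of the score tracks and were not analysed here, so the labels were not checked on them, and m6A was not measured in these libraries. Read depth is unknown.

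PPS were more numerous in the mta lists, and the excess lay in sites found with the dsRNase. The Col0 lists held 11282 and 9602 PPS (10442 ± 1188, SD, n = 2) and the mta lists 15436 and 11446 (13441 ± 2821, n = 2). Sites with a dsRNase call numbered 3768 and 6425 in Col0 (5097 ± 1879, n = 2) and 8699 and 8196 in mta (8448 ± 356, n = 2). Sites with an ssRNase call differed by less than the spread between replicates, at 8365 and 3711 in Col0 and 7912 and 4122 in mta. PPS covered 745 and 682 kb in Col0 (714 ± 44.9, n = 2) and 997 and 784 kb in mta (891 ± 150, n = 2). They touched exons of 2729 and 2206 genes in Col0 and 3459 and 2651 genes in mta. Chloroplast PPS numbered 738 and 454 in Col0 and 707 and 397 in mta, and mitochondrial PPS 288 and 244 against 289 and 240. Without mta replicate 1 the excess of mta was 1004 PPS and 70.7 kb, and without mta replicate 2 it was 4994 PPS and 283 kb, against 2999 PPS and 177 kb with all lists. In exact permutation tests, PPS number, covered length and dsRNase sites each gave p = 0.333, the smallest that 2 lists against 2 allow, and genes with PPS gave p = 0.667. Col0 replicate 1 stood apart from the other lists in the share of its PPS with a dsRNase call, 33.4% against 66.9% in Col0 replicate 2 and 56.4% and 71.6% in mta.

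**Figure D1:**
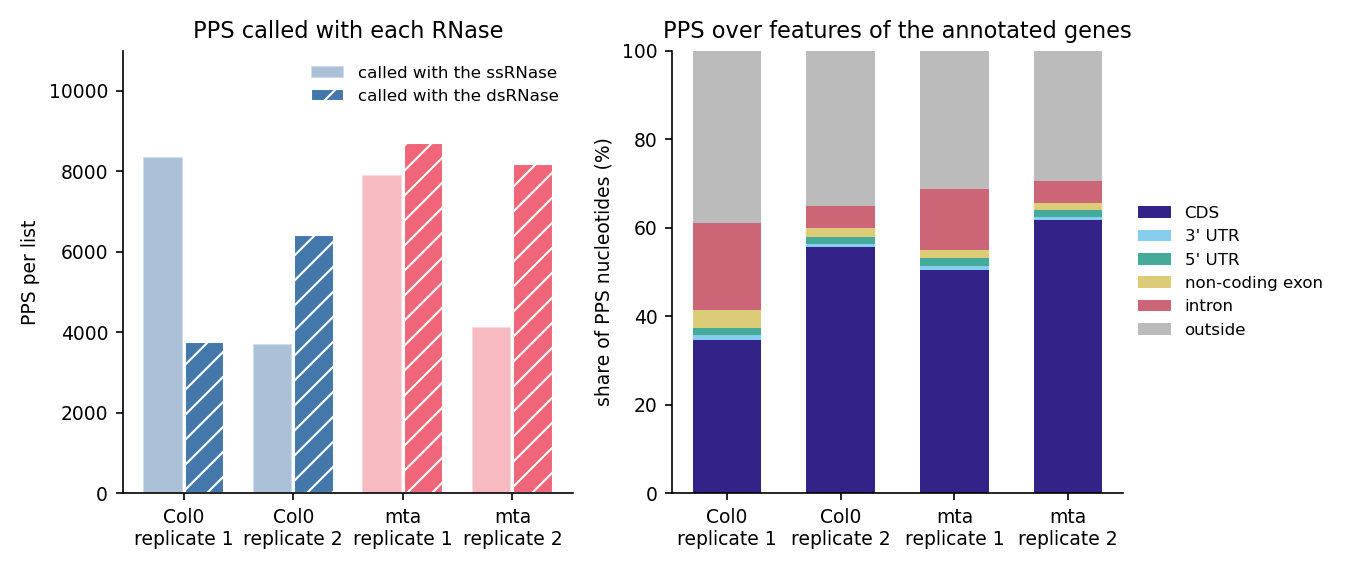
Number of PPS called with each RNase in each of the 4 lists (left; Col0 blue, mta red, a site called with both RNases counted in both bars) and share of PPS nucleotides (%) over features of the annotated genes (right). dsRNase PPS numbered 8699 and 8196 in mta and 3768 and 6425 in Col0, and the CDS held between 34.6% and 61.7% of PPS nucleotides.

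Coding sequence held most exonic PPS nucleotides in every list, and 3′ UTRs held few. The CDS took 34.6% and 55.7% of PPS nucleotides in Col0 (45.2 ± 14.9, SD, n = 2) and 50.3% and 61.7% in mta (56.0 ± 8.06, n = 2), with p = 0.667 in the exact permutation test. PPS covered 20.04 and 29.46 nucleotides per kb of annotated CDS in Col0 and 38.94 and 37.58 in mta (exact permutation p = 0.333). The 3′ UTR, where m6A is known to concentrate, took 1.08% and 0.653% in Col0 and 1.06% and 0.632% in mta, and the 5′ UTR took 1.502% and 1.648% in Col0 and 1.799% and 1.592% in mta. Introns took 19.7% and 5.03% in Col0 and 14.0% and 4.87% in mta, so that the lists of replicate 1 held the higher value in both genotypes. Nucleotides outside the genes of the tracks took 39.0% and 35.1% in Col0 and 31.1% and 29.5% in mta (exact permutation p = 0.333). dsRNase PPS lay in the CDS for 51.1% and 78.0% of their nucleotides in Col0 and 73.4% and 77.5% in mta. ssRNase PPS lay in introns for 26.0% and 11.8% of their nucleotides in Col0 and 25.4% and 12.1% in mta. Without Col0 replicate 1 the CDS share of mta exceeded that of Col0 by 0.375 percentage points, against 10.9 with all lists.

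The lists resembled each other by replicate number as much as by genotype. The Jaccard index of PPS nucleotides was 0.308 between the Col0 lists and 0.402 between the mta lists. Between genotypes it was 0.341 for the lists numbered 1, 0.412 for those numbered 2, and 0.285 and 0.336 across numbers. For ssRNase PPS, lists with the same number gave 0.4071 and 0.3996 and all other pairs 0.303 to 0.318. For dsRNase PPS, the mta lists gave 0.407, and Col0 replicate 1 gave 0.189 to 0.195 with each of the other lists. PPS nucleotides found in both replicates added up to 336 kb in Col0 and 511 kb in mta.

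Among genes with PPS in a single genotype, most had them in mta. PPS lay on exons of 294 genes in both mta lists and neither Col0 list, and of 55 genes in both Col0 lists and neither mta list. The mta lists are longer, and with all lists thinned at random to 9602 PPS these counts were 210 and 100 (medians of 100 draws). The split by replicate number gave 362 such genes (323 and 39) and the crossed split 158 (66 and 92), against 349 for the genotype split. The order of the splits depended on the rule: at least 20 covered nucleotides gave 357 genes by genotype against 267 and 157, and stricter PPS gave 241 against 224 and 131, while gene bodies gave 331 against 541 and 143. With dsRNase PPS alone, 363 genes had PPS in mta only and 34 in Col0 only, against 132 and 151 genes in total for the other splits. With ssRNase PPS alone the numbers were 88 and 41, against 510 genes for the split by replicate number. A total of 1400 genes had PPS in all 4 lists. Leaving out a list eases the rule, and the count of 349 then became 782 without Col0 replicate 1, 1035 without Col0 replicate 2, 684 without mta replicate 1 and 1000 without mta replicate 2. In the same order, genes in mta only numbered 601, 595, 487 and 894, and genes in Col0 only 181, 440, 197 and 106.

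The genes named below were picked by covered length, and no gene group was tested for enrichment among the genes of a single genotype. EDA9 (AT4G34200), a phosphoglycerate dehydrogenase of serine synthesis, had 361 and 487 exonic nucleotides in PPS in the mta lists (424 ± 89.1, SD, n = 2) and was listed at 0 in both Col0 lists. Its PPS were dsRNase sites in the CDS, such as chromosome 4, 16375081 to 16375138 in replicate 1 and 16375077 to 16375127 in replicate 2. NdhM (AT4G37925), a subunit of the chloroplast NADH dehydrogenase-like complex, had 201 and 257 nucleotides (229 ± 39.6, n = 2), with a site on chromosome 4 at 17830814 to 17830870 in replicate 1 and 17830814 to 17830948 in replicate 2. IDH-V (AT5G03290), a subunit of mitochondrial isocitrate dehydrogenase, had 199 and 239 nucleotides, with a dsRNase site on chromosome 5 at 795539 to 795611 and 795539 to 795608. CAD9 (AT4G39330), of the cinnamyl alcohol dehydrogenase family, had 160 and 283 nucleotides, ENODL17 (AT5G15350) 195 and 219, and SKS6 (AT1G41830) 256 and 188. AT1G52000 had 399 and 488 nucleotides, AT3G05900 167 and 315, AT5G01590 249 and 149, and ATG2 (AT3G51800) 276 and 112. Only exons were counted: CAD9 and ENODL17 also had an intronic PPS in Col0 replicate 1, and ATG2 had intronic PPS in every list.

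Among the genes with exonic PPS in Col0 only, GDI2 (AT3G59920), a Rab GDP dissociation inhibitor, had 103 and 124 nucleotides in the Col0 lists (114 ± 14.8, n = 2) and was listed at 0 in mta. Its site on chromosome 3 at 22136086 to 22136166 was called with the ssRNase in replicate 1 and that at 22136058 to 22136144 with the dsRNase in replicate 2. CK1 (AT1G71697), a choline kinase, had 91 and 135 nucleotides, and ZIF1 (AT5G13740), a transporter in zinc tolerance, had 55 and 137. CK1 also had an intronic ssRNase PPS in mta replicate 1. PIN1AT (AT2G18040), a prolyl isomerase, had 159 and 44 nucleotides, and AT4G28300 172 and 51. AT1G11210 had 68 and 120, AT1G54320 123 and 42, AT1G27200 95 and 67, and AT5G48385 105 and 56. For ZIF1, AT1G54320 and AT5G48385 no site overlapped between the Col0 lists, so their values do not show the same stretch protected in both replicates.

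**Figure D2:**
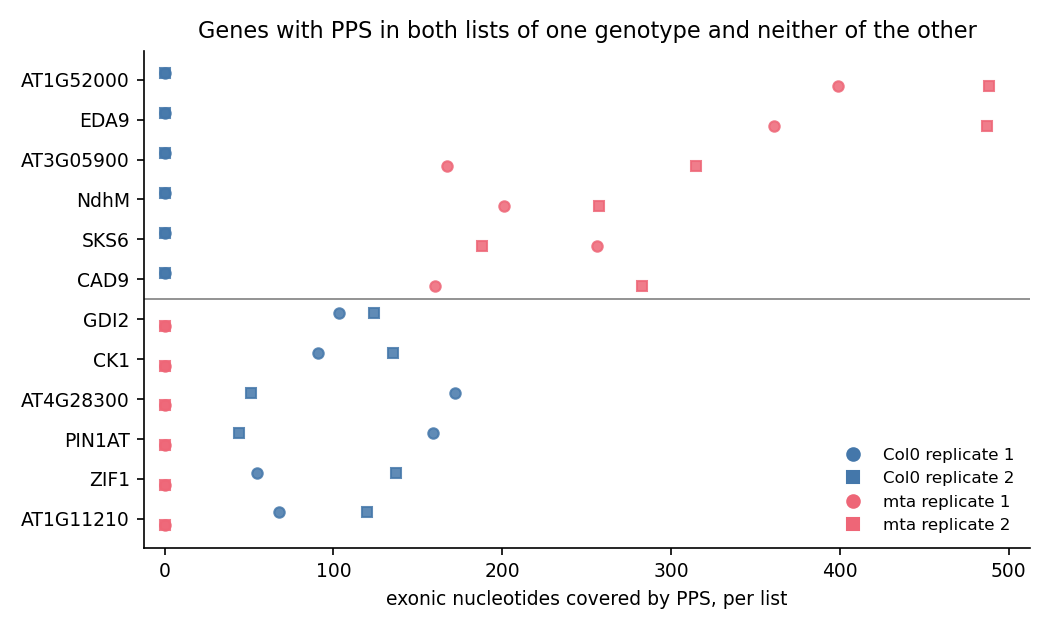
Exonic nucleotides covered by PPS in each of the 4 lists (circles replicate 1, squares replicate 2; Col0 blue, mta red) for the 6 genes with the highest mean in mta only and the 6 in Col0 only. EDA9 reaches 487 nucleotides in mta, and GDI2 103 and 124 nucleotides in Col0.

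PPS coverage per gene was then compared by gene group, relative to the total of each list. Photosystem and light-harvesting genes, which were covered over a median of 58.8% of their exons, were lower in mta for 25 of 28 tested members, with a median log2 change of -0.51 (0.0484 without scaling) against 0.11 for all tested genes. The list passed camera with the preset correlation (adjusted p = 4.8e-05) and did not with an estimated correlation (adjusted p = 0.872). PSBR, a photosystem II subunit, was covered over 473 and 468 nucleotides in Col0 and 338 and 408 in mta (log2 change -0.88, SE 0.31), and LHCB2.1 over 831 and 841 against 578 and 840 (-0.82, SE 0.33). The 3 members above 0 were LHCB1 genes, whose near-identical copies can share reads and are uncertain, such as LHCB1.1 with 665 and 0 nucleotides in Col0 and 273 and 380 in mta. Without Col0 replicate 1 the median of the list was -0.15 (adjusted p = 0.762), without mta replicate 1 it was -0.38 (adjusted p = 0.0946), and without Col0 replicate 2 it was -0.91 with all 28 members lower (adjusted p = 8.78e-12, and adjusted p = 0.742 with an estimated correlation). Without scaling of the lists the sign of this median turned, 9 of 28 members were lower and the list no longer passed (adjusted p = 0.118, still placed below other genes), as the median of all genes moved from 0.11 to 0.55.

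Genes encoded in the organelles were also lower in mta relative to other genes, as lists added after the data were seen. Chloroplast-encoded genes were lower for 43 of 58 members (median log2 change -0.71, adjusted p = 0.0015, and adjusted p = 0.872 with an estimated correlation). Mitochondrion-encoded genes were lower for 36 of 43 members (median -0.41, adjusted p = 0.0015, and adjusted p = 0.872 with an estimated correlation), and without scaling their median was 0.03. ATCG00020 was covered over 1062 and 790 nucleotides in Col0 and 0 and 394 in mta, and ATCG00280 over 1417 and 576 against 0 and 439. Without Col0 replicate 1 the medians were -0.31 (adjusted p = 0.8502) for the chloroplast and -0.12 (adjusted p = 0.729) for the mitochondrion, and without Col0 replicate 2 they were -1.45 and -0.85. Without mta replicate 2 the chloroplast median was -0.42 and the mitochondrial median -0.32 (adjusted p = 0.0737).

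**Figure D3:**
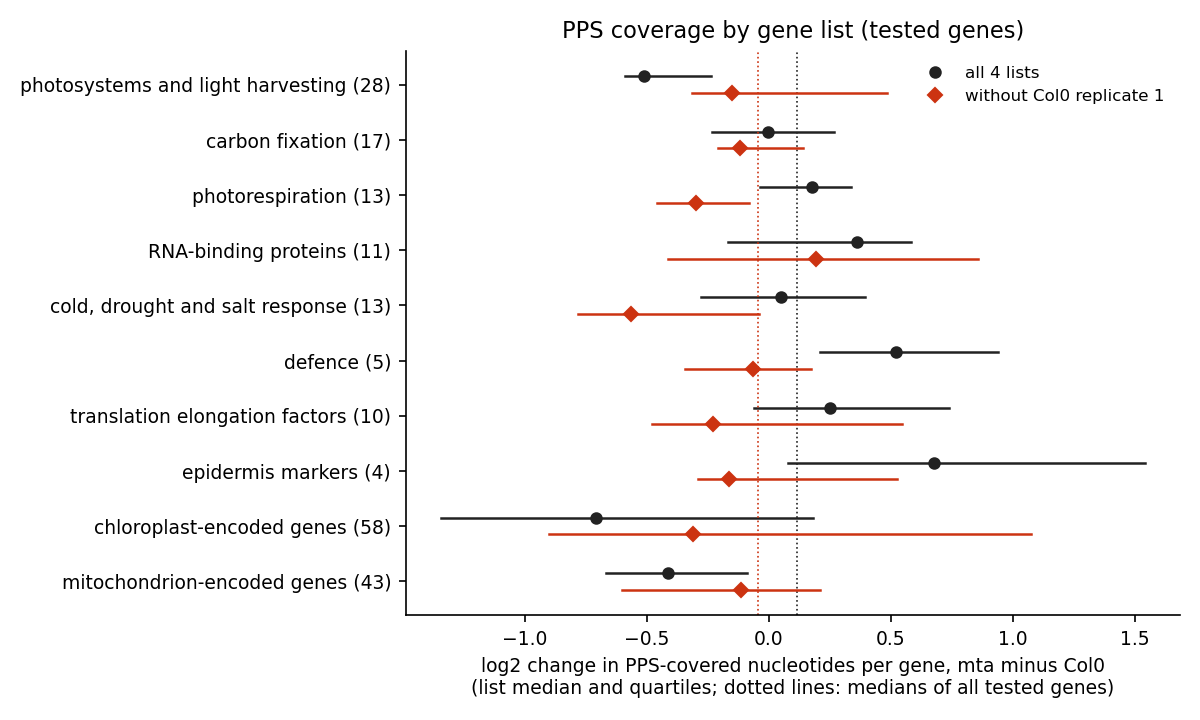
Median and quartiles of the log2 change in PPS coverage (mta minus Col0) for gene lists with at least 3 tested members (numbers in brackets), with all 4 lists (black) and without Col0 replicate 1 (red). The photosystem list lies at -0.51 with all lists, at -0.15 without Col0 replicate 1, and at 0.0484 without scaling (not drawn).

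The other lists did not pass, with adjusted p-values from 0.337 to 0.804. Of the 17 carbon fixation genes 8 were higher and 9 lower in mta (median 0.00, adjusted p = 0.712), and all 17 were higher without scaling (median 0.56). GAPA, a subunit of chloroplast glyceraldehyde-3-phosphate dehydrogenase, was covered over 304 and 303 nucleotides in Col0 and 935 and 920 in mta (log2 change 0.99, SE 0.27, adjusted p = 0.325 in limma). RPI3, a ribose-5-phosphate isomerase, had 185 and 273 against 604 and 477 nucleotides (0.64, SE 0.28), CP12-2 had 68 and 338 against 399 and 403 (0.73, SE 0.69), and RCA, the activase of Rubisco, 1552 and 1140 against 1336 and 1375 (-0.55, SE 0.36). Of 13 photorespiration genes 8 were higher (median 0.18, adjusted p = 0.804), against 13 without scaling (median 0.69), 2 without Col0 replicate 1 (median -0.30) and 4 without mta replicate 2 (median -0.17). Higher with all lists were PGLP1 at 132 and 735 against 677 and 770 nucleotides, GLDT at 223 and 547 against 715 and 674, and GLYK at 0 and 98 against 83 and 40. GLN2, at 1026 and 1110 against 1027 and 1328, was lower after scaling (log2 change -0.44, SE 0.27). Of 10 translation elongation factors 6 were higher (median 0.25, adjusted p = 0.646), against 10 without scaling (median 0.81) and 4 without Col0 replicate 1 (median -0.23). EF-Ts had 117 and 177 nucleotides in Col0 and 496 and 315 in mta (0.81, SE 0.34), EF1B-alpha 53 and 95 against 326 and 154, EF1B-gamma 54 and 180 against 190 and 267, and EF1B-beta was listed at 0 in Col0 with 112 and 72 in mta. The camera test sets a list against the other tested genes, so its direction is not the sign of the list's own change. It was lower for photorespiration (mean 0.13), carbon fixation (mean 0.04) and the cold, drought and salt list (median 0.05, mean -0.16).

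Of the m6A list, 2 of 10 genes in the tracks had PPS in at least 2 lists, and both were above 0 (median 0.93, adjusted p = 0.612), while without mta replicate 1 the single tested gene was at -1.02. ALKBH10B, an m6A demethylase, was listed at 0 in Col0 and had 69 and 44 nucleotides in mta. It entered the test through its mta lists alone, so its sign was fixed by the filter. ECT2, an m6A reader, had 34 and 105 against 265 and 31 (log2 change 0.12, SE 1.00). Of 11 tested RNA-binding proteins 7 were higher (median 0.36, adjusted p = 0.804), against 4 of 8 with stricter PPS (median -0.09). CP31B, a chloroplast RNA-binding protein, had 13 and 0 nucleotides in Col0 and 108 and 84 in mta (1.84, SE 0.67), FCA had 24 and 0 against 70 and 32, GRP7 227 and 209 against 178 and 210, and CSP2 176 and 104 against 167 and 52. Of 13 cold, drought and salt genes 8 were higher (adjusted p = 0.635), against 10 without scaling (median 0.59), 3 without Col0 replicate 1 (median -0.56, adjusted p = 0.0636), 5 without mta replicate 2 (median -0.11) and 6 with stricter PPS (median -0.32). KIN1 had 122 and 180 nucleotides against 0 and 89, COR414-TM1 32 and 133 against 25 and 26, COR6.6 223 and 231 against 158 and 221, and RD20 82 and 274 against 270 and 514. The 5 tested defence genes were higher (median 0.52, adjusted p = 0.712; median -0.06 without Col0 replicate 1), with PDF1.2 at 0 and 89 against 114 and 152, WRKY70 at 0 and 117 against 98 and 103, WRKY33 at 38 and 87 against 175 and 103, and PR5 at 248 and 522 against 418 and 727.

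Markers of cell types and smaller lists held few tested genes. The companion-cell genes SUC2 (1091 and 589 against 548 and 775 nucleotides) and AHA3 (1062 and 483 against 675 and 592) were the 2 tested members of the guard cell and vascular list (median -0.80, adjusted p = 0.337), with medians of -0.11 without Col0 replicate 1 and -1.50 without Col0 replicate 2. Of 4 epidermis markers 3 were higher (median 0.67, adjusted p = 0.701), against a single gene each without Col0 replicate 1 (median -0.16) and without mta replicate 2 (median -0.17): the wax gene CER1 was listed at 0 in Col0 with 238 and 44 in mta, FDH had 27 and 354 against 338 and 492, CER6 147 and 620 against 409 and 605, and LTP1 197 and 309 against 335 and 380. The clock genes LNK2 (42 and 0 against 131 and 74) and PRR7 (53 and 0 against 105 and 21) had a median of 0.94 (adjusted p = 0.712), and -0.13 without Col0 replicate 2. TTG1, a trichome regulator, had 0 and 53 against 52 and 49 nucleotides (adjusted p = 0.804 for its list; log2 change 0.66, and -0.33 without Col0 replicate 1).

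Across 3070 tested genes, limma called 0 genes at an adjusted p of 0.05, and 420 genes had an unadjusted p under 0.05, of which 331 were higher in mta. Without scaling these were 493 genes, 443 of them higher. The smallest adjusted p, 0.325, was shared by many genes, GAPA among them. No member of any list passed, adjusted over the list alone or over all genes tested. The split by replicate number gave 217 genes at an unadjusted p under 0.05 and the crossed split 40, and neither called a gene. Without mta replicate 2 the spread comes from the Col0 lists alone, and 5 genes passed, all lower in mta and named after their values were seen: GTR2, a glucosinolate transporter, and ATCG00020, ATCG00280, ATCG00490 and ATCG00680, each listed at 0 in the mta list left. In mta replicate 2 they had 119, 394, 439, 1227 and 76 nucleotides, and ATCG00490, at 1440 and 611 in Col0, was thus within the range of Col0. PPS with their midpoint on the opposite strand of ATCG00490 had summed lengths of 1264 and 825 nucleotides in Col0 and 1453 and 830 in mta. These lengths include parts outside the gene and are not its covered nucleotides. Genes at an unadjusted p under 0.05 then numbered 42, and 59 without mta replicate 1. With all 4 lists, the test recovered 62.1% of simulated log2 changes of 4 and 3.03% of changes of 2, and recovery with a list left out was not simulated. These changes ignored the floor set by the pseudocount and the limit set by exon length. Tested genes were covered over a median of 5.09% of their exons, and a gene with little coverage cannot fall by 4. The recovery of changes that such genes can show is therefore not known.

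Structure scores of both genotypes correlated above 0, but weakly, along most transcripts. The tracks correlated at a median of 0.302 per transcript (quartiles 0.181 and 0.415), and the correlation was above 0 for 94.5% of 9556 genes (95% interval 94.0 to 94.9). Chloroplast-encoded genes had a median of 0.693 and mitochondrion-encoded genes 0.491. Carbon fixation genes stood highest among the lists fixed in advance, with a median of 0.566, above all 10000 matched random lists, and RBCS3B, a small subunit of Rubisco, reached 0.827, GAPA2 0.776 and RCA 0.749. Elongation factors had a median of 0.536 (percentile 99.99; EF-Ts 0.709), cold, drought and salt genes 0.483 (99.99; COR15A 0.711), photosystem genes 0.4498 (99.99; LHCA1 0.763 and LHCA4 -0.236) and photorespiration genes 0.442 (99.58; CAT2 0.663). The medians of the m6A list (0.289), the clock (0.277), defence (0.338), trichome (0.361), guard cell and vascular (0.332), RNA-binding (0.382) and epidermis lists (0.439) lay between percentiles 25.47 and 97.53. Correlations are across the nucleotides of pooled tracks, no replicate gives a reference for them, and reads per transcript, which may affect them, were not measured here.

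By region, 3′ UTRs had higher scores in mta by a small margin. Because scores are centred per transcript, a higher UTR score goes with a lower CDS score by construction, and both are read here as a single shift. The 3′ UTR mean was -0.106 in Col0 and -0.0802 in mta (mean difference 0.0258 ± 0.677, SD over 8328 genes), and 53.0% of genes were higher in mta (95% interval 52.0 to 54.1). The 5′ UTR mean was -0.152 in Col0 and -0.129 in mta, with 51.7% of 7143 genes higher (50.5 to 52.9). The CDS mean was 0.0121 in Col0 and 0.00549 in mta, with 47.7% of 9094 genes higher (46.7 to 48.7). Upstream of the start codon, mean scores were higher in mta between 40 and 31 nucleotides before it (-0.183 in Col0 and -0.0772 in mta), and lower in mta over the first 10 coding nucleotides (-0.137 and -0.190). Both tracks had their lowest mean in the last 10 nucleotides before the start codon (-0.225 and -0.219). After the stop codon, scores were highest at 20 to 29 nucleotides in mta (0.0739) and at 30 to 39 nucleotides in Col0 (0.00247). With a single pooled track per genotype, none of these differences has a replicate check.

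**Figure D4:**
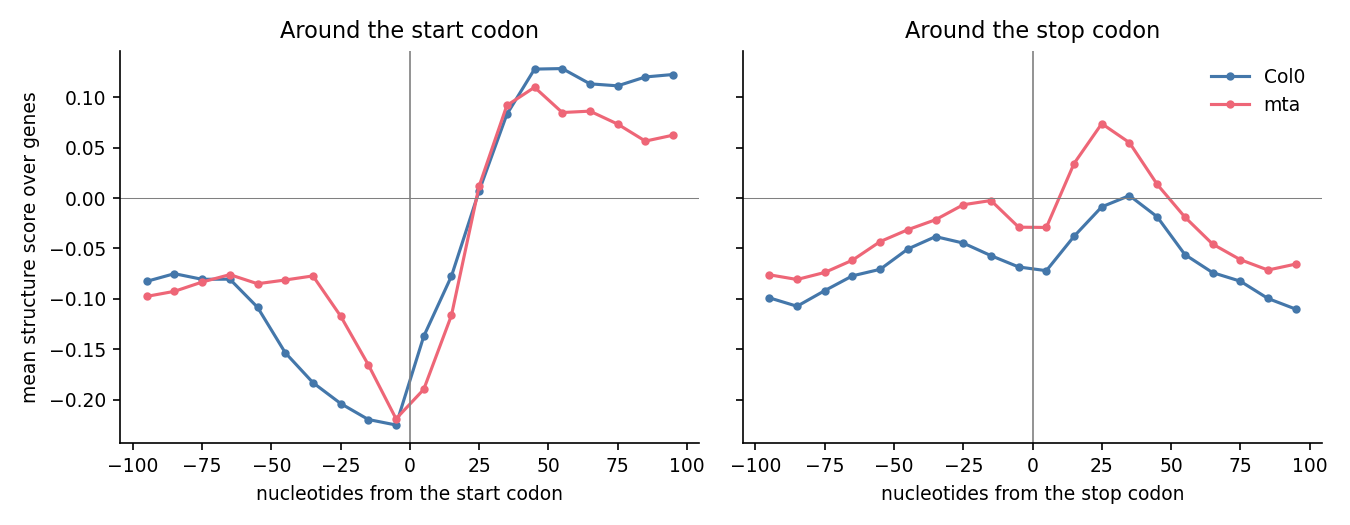
Mean structure score over genes in steps of 10 nucleotides around the start codon (left) and the stop codon (right) for Col0 (blue) and mta (red), without error bars because each genotype has a single pooled track. Both tracks dip just before the start codon, to -0.225 in Col0 and -0.219 in mta.

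Gene lists differed in the balance of scores between UTRs and CDS, which the centring ties together. In photosystem genes the CDS score was lower in mta for all but 2 of 28 members (median -0.0879, percentile 0.52 among random lists) and the 3′ UTR score higher for 24 of 28 (median 0.187, percentile 87.8), with PSBR at -0.164 in the CDS and 0.353 in the 3′ UTR. Cold, drought and salt genes had a median CDS difference of -0.0914 (percentile 1.42), with COR6.6 at -0.366 and ERD14 at -0.214. The m6A list had a lower 3′ UTR score in mta (median -0.453, percentile 2.04, 2 of 8 members above 0). The writer-complex subunit VIR was at -1.41 (148 scored nucleotides) and the readers ECT4 at -1.66 (42) and ECT3 at -0.883 (171). Against these, ECT1 was at 1.18 (113) and the demethylase ALKBH9B at 1.79 (28). The members with the most scored nucleotides were ECT2 (493) at -0.143 and ALKBH9C (238) at -0.630. The guard cell and vascular list had a higher 3′ UTR score (median 0.856, percentile 99.2, all 5 members above 0), with SUC2 at 1.097, APL at 0.950 and AHA3 at 0.856. The defence list had a median 5′ UTR difference of 0.754 (percentile 98.3). These percentiles are extremes over many lists and regions, some of which arise by chance, and short UTRs give wide differences. The random lists were matched on whole transcripts and not on the length of the region, so region length is not controlled. Among 1673 genes with long 3′ UTRs, the largest differences were higher in mta for AT1G20880 (1.397), AT4G39960 (1.34), IRX9-L (1.33), AT1G48090 (1.22) and YLMG1-1 (1.198). They were lower for the cycloartenol synthase CAS1 (-1.42), the chloroplast sensor kinase CSK (-1.33), AT5G09460 (-1.32), AT1G10020 (-1.14) and AT3G60410 (-1.14).

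Inside PPS, scores depended on the RNase with which the sites were found. ssRNase PPS found in both replicates had a lower score inside than in their flanks at 63.3% of 496 sites in Col0 (95% interval 58.9 to 67.6) and 74.0% of 772 sites in mta (70.7 to 77.0). dsRNase PPS had a lower score inside at 27.0% of 1033 sites in Col0 (24.3 to 29.8) and 37.9% of 3362 sites in mta (36.3 to 39.6), so that most lay in stretches of higher score. Over all PPS, both genotypes gave 43.9% lower inside, but Col0 sites turned to 58.3% in the mta track, and single lists reached 49.1% in Col0 and 49.9% in mta. In their own tracks, mean scores inside and in the flanks were 0.0723 ± 0.500 and -0.00438 ± 0.510 (SD over 1762 sites) in Col0 and 0.0522 ± 0.531 and -0.0224 ± 0.595 (3982 sites) in mta. In the track of the other genotype, dsRNase sites of Col0 were lower inside at 48.7% (45.6 to 51.8), and in Col0 replicate 2 alone at 42.6% in their own track.

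**Figure D5:**
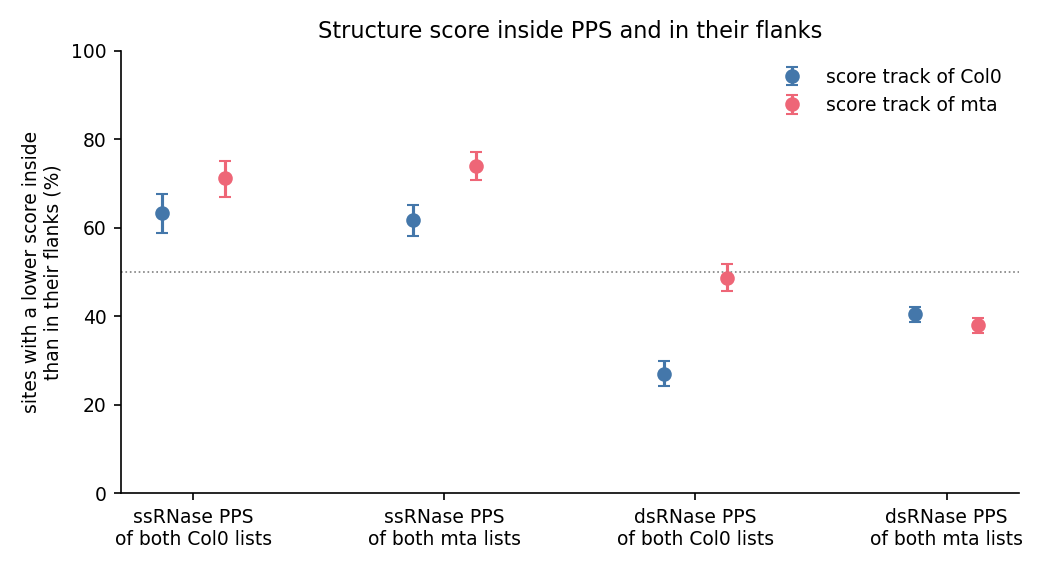
Percentage of PPS with a lower mean structure score inside than in flanks of equal length, for ssRNase and dsRNase PPS found in both lists of a genotype, in the Col0 track (blue) and the mta track (red), with exact 95% binomial intervals over sites. dsRNase sites of Col0 lie at 27.0% in the Col0 track and at 48.7% in the mta track.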

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

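The tests of scaling, of leaving out Col0 replicate 1 for the photosystem genes and of the other genotype's score track were chosen only after the result was seen.

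PPS on the opposite strand of exons, judged only by the genes of the tracks, were not used in any comparison. They numbered 214 and 126 in Col0 and 224 and 81 in mta, without a background count to set them against. Of these, 33, 22, 25 and 10 lay on nuclear genes and the others on organelle genes.

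Exonic PPS lay in both mta lists alone for 294 genes and in both Col0 lists alone for 55. With every list thinned at random to 9602 PPS, the ratio of these counts had a median of 2.11 (1.84 to 2.48 in 95% of 100 draws), while thinned lists of replicate 1 alone shared 216 genes and those of replicate 2 alone 98.5. The tables argue against Col0 replicate 1 as the whole source: in thinned lists without it, the mta lists alone shared 1.70 times as many genes (1.58 to 1.84) as Col0 replicate 2 shared with a single mta list. The longer mta lists may account for part of the excess. The ratio of 2.11 is left with PPS number equalised, but thinning did not equalise the share of PPS on exons. By midpoint, exons held 4947 of 11282 and 5917 of 9602 PPS in Col0, and 8778 of 15436 and 7657 of 11446 in mta. That share and genotype cannot be told apart, because the split by replicate number stood as far apart and there are 2 lists per genotype.

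Photosystem and light-harvesting genes had a median log2 change of -0.51 (quartiles -0.59 and -0.24), 0.63 below all tested genes. High coverage of these transcripts, at a median of 58.8% of their exons, was set against random lists matched on covered share. Those lists had a median of -0.28, and the photosystem median lay at percentile 0.29 of them. They were drawn gene by gene, while photosystem genes varied together between replicates (estimated correlation 0.887). The percentile therefore cannot decide whether high coverage is the whole cause. Without scaling the photosystem median was 0.0484 (adjusted p = 0.118 in camera), so its sign rests on the scaling. The gap of -0.50 to all genes without scaling says nothing about the source of the gap, because scaling moves nearly all genes alike and could not have closed it. Without Col0 replicate 1 the median was -0.15 (adjusted p = 0.762), which is consistent with that list as a source of the shift, and a difference between the genotypes stays open.

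ssRNase PPS had lower and dsRNase PPS higher structure scores than their flanks, and the structure-only libraries behind the scores may also have served as background for the site calls. The track of the other genotype rests on libraries that did not enter the calls. In it, ssRNase sites were lower inside at 71.2% (Col0 sites) and 61.7% (mta sites), and dsRNase sites of mta at 40.4%. For these sites, this argues against noise of the shared libraries as the sole source. A structure-only signal common to both genotypes is not excluded as a source, because it would carry over to the other track. dsRNase sites of Col0 stood at 48.7% there (interval 45.6 to 51.8), against 27.0% in their own track, which is consistent with shared libraries as a source, but the single lists parted there, at 39.0% for Col0 replicate 1 and 55.7% for Col0 replicate 2, so this stays open. Digestion by each RNase, which favours sites of different pairing, stays open, and no biological explanation was tested.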

How the results depend on the processing

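Settings by RNase, nuclear chromosomes only, no scaling with dsRNase PPS, the other genotype's track, rank correlation, medians of region scores, genes with all 3 regions, and leaving out lists for gene lists and for genes in a single genotype were chosen only after the result was seen.

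Of 1188 alternatives to 94 results, those that turned a difference between PPS lists or a share of sites come first. With ssRNase PPS alone, mta lists held -21 PPS relative to Col0 and 4.83 kb more, against 2999 PPS and 177 kb with both RNases. In the mta track, PPS of both Col0 lists were lower inside at 58.3% of sites. The overlap within genotypes over that between genotypes was 1.03, with 0.890 for ssRNase PPS and 1.15 for dsRNase PPS. Medians of gene lists also turned in sign, several with a list left out or without scaling, and that of epidermis markers from 0.67 to -0.78 with ssRNase PPS. The cause was not tested for any value in this part, except that leaving out a list eases the rule for genes in a single genotype.

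Genes with PPS in a single genotype were 129 with ssRNase PPS alone and 684 to 1035 with a list left out. Those in mta only were 88 with ssRNase PPS and 487 to 894 with a list left out, and those in Col0 only 34 with dsRNase PPS and 106 to 440 with a list left out.

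limma called 0 genes in every other setting and 0 to 5 with a list left out. The replicate block called 0 genes too (431 at an unadjusted p under 0.05) and the same-numbered lists deviated together at a correlation of 0.152, with 2 pairs. Of 14 gene lists, 3 passed, against 1 with ssRNase PPS, dsRNase PPS (scaled or not) or nuclear chromosomes alone (where organelle lists drop out by construction), 0 with an estimated correlation (adjusted p = 0.872 each) and 0 to 4 with a list left out; the replicate block changed no call of the 3 lists. For photosystems the adjusted p was 0.118 without scaling, 0.442 with ssRNase PPS and 8.78e-12 to 0.762 with a list left out. For chloroplast-encoded genes it was 0.0747 with ssRNase PPS, 0.573 with dsRNase PPS, 0.158 with unscaled dsRNase PPS and 7.89e-16 to 0.8502 with a list left out. For mitochondrion-encoded genes these were 0.183, 0.462, 0.259 and 4.69e-06 to 0.729.

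With medians of region scores, 51.3% of 3′ UTRs, 50.5% of 5′ UTRs (interval 49.4 to 51.7) and 43.4% of CDSs were higher in mta, and 46.5% of CDSs among genes with all 3 regions. Centring each track on its median, 0.01 in both, leaves these differences as they are by construction. Such centring also leaves correlations along whole transcripts unchanged, and the median score per transcript was not analysed here.

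All PPS were lower inside at 45.1% to 49.1% of sites with a single Col0 list and 44.2% to 49.9% with a single mta list. dsRNase sites were at 24.3% to 42.6% in Col0 and 39.1% to 41.7% in mta with a single list, and at 48.7% (Col0) and 40.4% (mta) in the other track. ssRNase sites were at 62.1% to 66.0% in Col0 and 69.6% to 71.4% in mta with a single list, and at 71.2% and 61.7% in the other track.

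The CDS share of mta exceeded that of Col0 by 0.375 to 21.4 percentage points with a list left out. Among the 52 named genes with a log2 change, 77 of 774 alternatives had the other sign, with no call. Translation elongation factors passed with ssRNase PPS alone (adjusted p = 0.0486, and adjusted p = 0.593 with an estimated correlation), and guard cell and vascular markers without Col0 replicate 2 (adjusted p = 0.0378, and adjusted p = 0.742 with an estimated correlation), against 0.762 without Col0 replicate 1. Unknown depth limits what a listed 0 shows, and the RRACH alternatives were not run.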

Other observations

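The gene groups and rankings below were chosen only after the result was seen.

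PPS in introns lay in 2091 genes, and 242 genes had them in all 4 lists. Sites with their midpoint in an intron numbered 2402 and 535 in Col0 and 2216 and 601 in mta, and nearly all were called with the ssRNase (2389 and 529 in Col0, 2197 and 597 in mta). BGAL1, a beta-galactosidase, held 14 and 12 intronic PPS in Col0 and 15 and 9 in mta. BBD1, a bifunctional nuclease, held 8 and 4 against 7 and 1, and the triose phosphate translocator APE2 held 5 and 2 against 6 and 4. The calcium exchanger CAX1 held 6 and 4 against 5 and 5, and the light-harvesting gene LHCB5 held 1 and 4 against 3 and 2. Of the genes with PPS on the opposite strand of their exons, 36 had them in all 4 lists, among them 6 nuclear genes such as RAP and HISN5B.

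Among the genes with the most nucleotides in PPS, the transporter PEN3 was covered over 1121 and 1790 nucleotides in Col0 and 1941 and 2217 in mta, and the chaperone CLPC1 over 1046 and 2021 against 1870 and 2109. GUN5, a subunit of magnesium chelatase, had 1277 and 1402 against 2235 and 2126 nucleotides, and the methionine synthase ATMS1 had 1234 and 1242 against 1740 and 2114. GLDP1, of the glycine decarboxylase complex, had 905 and 1359 against 1705 and 2244, GLU1 710 and 1748 against 1521 and 1783, the catalase CAT3 1431 and 1304 against 1311 and 1582, and the transketolase TKL1 896 and 1506 against 1280 and 1702. None of these genes passed the limma test.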
